A study of Mus musculus with 3 samples.

How the data were processed

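Total RNA of OCCM-30 mouse cementoblasts was sequenced after 0, 7 and 14 days in cementogenic medium, with 1 library per time point and per table. Each deposited column was assigned to a time point by its name and the sample titles. Per the submitters' processing notes, HISAT2, TopHat, Cufflinks, HTSeq and DESeq were used with the mm10 build of the mouse genome; their versions, order and roles, the strand setting of the counting, the miRNA aligner and the miRBase release are not given in the sources used here.

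The deposited gene table held raw whole-number counts for 46095 genes made by the authors, with locations used here as listed (mm10, counted from 1). The deposited FPKM values equalled the count divided by the listed gene length and the summed counts of the library, within a relative tolerance of 0.001, for 98.9%, 98.8% and 98.8% of detected genes on day 0, 7 and 14. Why the other genes differed was not tested. The deposited counts of mature miRNAs covered 1976 names, and the deposited TPM values were the count scaled to a constant for each library, with no length term; 0.380%, 0.471% and 0.286% of that constant was not in the listed counts of the libraries labelled day 0, 7 and 14. The miRNA data held 2 lines without a name or value in each unit, and these are not analysed here. Of the gene symbols, 41483 were matched to a RefSeq gene table, 39893 of them on the same chromosome, and 73.9% of those had the same start. A set of 1500 genes lay on alternate or unplaced scaffolds, where reads can be shared with the chromosomal copy.

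Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3. The gene factors were 1.08, 0.966 and 0.962 for day 0, 7 and 14, and the miRNA factors 0.864, 1.46 and 0.795. With 1 library per group no replicated test was possible. Each comparison used the log2 ratio of CPM with a pseudocount of 0.5 CPM, and the exact Clopper-Pearson 95% interval of the ratio of counts, conditional on their sum. Features counted as different had 1 CPM or more in the higher library (10 for miRNAs), a ratio of at least 2 and an interval that excluded 1. The folds printed are ratios of scaled counts without the pseudocount, while the log2 ratios include it and understate changes of low genes. A count of 0 was set to a floor of 3 counts per library, which stood at 0.211, 0.221 and 0.216 CPM for genes on day 0, 7 and 14 and at 0.0996, 0.0717 and 0.185 CPM for miRNAs. Of all genes, 20902, 20414 and 20869 had a count on day 0, 7 and 14, and of the miRNAs 1665, 1784 and 1414. Long non-coding RNAs were 11716 genes that the table types so, or types as other non-coding or unknown where GENCODE or RefSeq gives a long non-coding class.

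The comparisons, 37 lists of genes and 13 of miRNAs, the rule for named features and the alternatives were fixed before the data were examined. A list's measured members had a mean of 1 CPM (10 for miRNAs), and its median was set among the medians of 10000 random lists of its size drawn from 20 bins of expression; no percentile was given for lists under 3 members. Named were the 10 genes of 10 CPM or more with the largest log2 ratio in each direction against day 0, and the first 5 for day 14 against day 7; the first 5 long non-coding RNAs of 2 CPM or more and the first 6 miRNAs of 100 CPM or more in each direction; the 10 most abundant miRNAs; and up to 4 members each by abundance and by ratio of every list. Runx2, Sp7, Alpl, Bglap, Bglap2, Ibsp, Spp1, Dmp1, Col1a1 and Mki67 were always named. Any other feature named is said to have been chosen after its values were seen. Some features that the rule takes are not reported here.

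The procedure was tested on simulated counts drawn from the means and totals of the libraries. Of 50 genes changed 2.5-fold, 88% were recovered for day 7 against day 0, 88% for day 14 against day 0 and 94% for day 14 against day 7; of 50 genes changed 1.5-fold, 0%, 2% and 0% passed the rule. Of 13844 unchanged genes, 5, 9 and 1 passed it. Of 25 miRNAs changed 2.5-fold, 100% were recovered in each of the 3 comparisons, and of 264 unchanged miRNAs 0 passed. These simulations hold counting error alone, so variation between cultures is not covered. The same scaling was used to draw and to call the counts, so error of the scaling is not covered either.

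The alternatives were DESeq2 1.42.0 size factors, total counts without a factor, no minimum or 5 times the minimum, pseudocounts of 0.1 and 2 CPM, a 4-fold threshold, and the authors' FPKM or TPM values. Alternatives chosen after seeing the data were miRNA libraries thinned to the smallest total, gene totals without mitochondrial and small structured RNA genes, and miRNA factors without the library labelled day 7. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Host genes of miRNAs, and the 3' untranslated regions searched for seed sites, came from the GENCODE mouse annotation of the same build. Those regions were the longest of each of 9027 protein-coding genes with a mean of 10 CPM or more. Seed families were used if they reached 1000 CPM and passed the size rule between the libraries labelled day 7 and day 0.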

Results

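OCCM-30 is an immortalised mouse cementoblast line, and cementoblasts are the cells that lay down cementum, the mineralised layer on the tooth root that anchors the periodontal ligament. The cells were kept in cementogenic medium for 0, 7 or 14 days, and total RNA was sequenced to find long non-coding RNAs, miRNAs and mRNAs that changed on the way. There was 1 library per time point for genes and 1 for mature miRNAs, so no difference had a replicate check and no p-value is given. Total gene counts were 13224690 on day 0, 14034518 on day 7 and 14439666 on day 14. The miRNA libraries labelled day 0, day 7 and day 14 held 34855863, 28729986 and 20443074 counts. Values are given as CPM, counts scaled by TMM factor and library total, and a gene is said to rise or fall where it passed a size rule of 2-fold with a 95% counting interval that excluded no change. The intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

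Whether the mineralisation programme of cementoblasts was switched on by 7 days in cementogenic medium was read from the comparison of day 7 with day 0. Sp7, the osteoblast transcription factor osterix (mm10 chromosome 15, 102356606 to 102367040), rose 23.1-fold (95% counting interval 19.4 to 27.5), from 9.70 to 224 CPM. Ibsp, the bone sialoprotein gene (chromosome 5, 104299287 to 104311472), rose 166-fold (75.9 to 453) from 6 counts, and Alpl, the tissue non-specific alkaline phosphatase gene (chromosome 4, 137741731 to 137796384), rose 3.77-fold (3.48 to 4.09). Runx2, the master regulator of the osteoblast lineage, had a log2 ratio of 0.92, and Spp1 (osteopontin) one of 0.65, both within 2-fold. Col1a1 was abundant throughout, at 8914 CPM on day 0, with a log2 ratio of 0.20. Dmp1, an osteocyte and dentin matrix gene, fell 3.68-fold (1.56 to 9.997) from 27 counts.

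Of 17 measured osteoblast and cementoblast transcription factors, 7 rose and 2, Twist2 and Atf4, fell. Mef2c rose 9.05-fold (8.18 to 10.05) and Dlx3 10.2-fold (6.11 to 18.3), while Twist2, a repressor of osteoblast maturation, fell 22.4-fold (11.6 to 49.8). Among 13 mineralised matrix genes 7 rose, and 1, Dmp1, fell, with Tnc (tenascin C) up 8.98-fold (8.44 to 9.56) and Sparc (osteonectin) up 2.74-fold (2.70 to 2.77). The median log2 ratio of that list was 1.26 (percentile 99.99 of random lists), and 0.77 with a pseudocount of 2 CPM. Bglap and Bglap2, near-identical osteocalcin copies whose reads can be split between them, stood at 29 and 68 counts on day 7, and their ratios are uncertain. Phosphate handling genes moved with the matrix genes: 6 of 11 rose and none fell, among them Phospho1, 3.46-fold (3.03 to 3.97), and Nt5e, 5.47-fold (4.99 to 6.02).

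**Figure D1:**
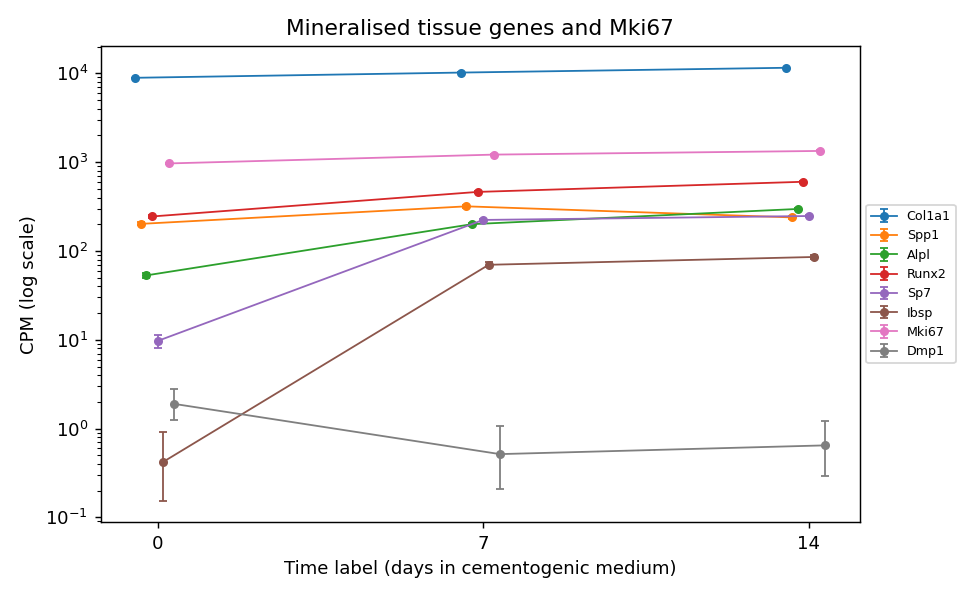
CPM on a log scale (vertical) against days in cementogenic medium (horizontal) for 8 genes, 1 library per point, with bars for exact 95% Poisson intervals of the count and points set slightly apart at each day for legibility. Ibsp and Sp7 climbed between day 0 and day 7 and stayed up on day 14, while Dmp1 stayed under 3 CPM.

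The largest increases on day 7 among genes of 10 CPM or more were outside the classical mineralisation genes. H19, an imprinted long non-coding RNA (chromosome 7, 142575530 to 142578146), went from 2 to 26182 counts, a ratio of 13738-fold (95% counting interval 3803 to 113450). Tnn, the tenascin W gene of bone and periodontal matrix, went from 1 to 5620 counts, 5898-fold (1058 to 233000). Wif1, a secreted Wnt inhibitor, rose 1744-fold (313 to 68933) from 1 count and Hspb7, a small heat shock protein gene of muscle, 1519.6-fold (272 to 60062) from 1 count. Hif3a, Hp (haptoglobin) and Lamc3, each with 0 counts on day 0, were at least 1078-fold, 770.0-fold and 577-fold higher against the floor of 3 counts per library. Serping1 (the C1 inhibitor), Selenbp1 and Car9 (a hypoxia-induced carbonic anhydrase) rose 251-fold (162 to 411), 447-fold (191 to 1378) and 205-fold (155 to 276).

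Among the genes that fell on day 7, Ccnd1 (cyclin D1) fell 251-fold (69.2 to 2079) to 2 counts, and Ccnd2 fell 32.2-fold (24.9 to 42.4). Vcam1, an adhesion molecule, fell 94.8-fold (43.3 to 259). The axon guidance genes Sema3a, Sema3c and Slit2 fell 69.3-fold (37.5 to 145), 71.6-fold (34.5 to 179) and 43.0-fold (27.4 to 71.8). Lgr6, an R-spondin receptor, Cd34, a progenitor surface marker, and Msln (mesothelin) fell 44.7-fold (27.4 to 78.7), 30.9-fold (23.9 to 40.8) and 35.4-fold (21.6 to 62.4). Samd12 went from 165 to 0 counts, at least 52.4-fold lower.

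Genes that respond to glucocorticoids had the highest median of the gene lists. On day 7 15 of 17 rose and none fell, with a median log2 ratio of 2.39. Tsc22d3 (GILZ) rose 6.12-fold (5.60 to 6.70), Per1 5.28-fold (4.84 to 5.76) and Cebpd 39.2-fold (27.3 to 58.3), and Zbtb16, with 0 counts on day 0 and 134 on day 7, was at least 46.9-fold higher. That median lay at percentile 100 of the medians of 10000 random lists of the same size matched on expression. The composition of the medium is not given in the sources used here.

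Of 22 small leucine-rich proteoglycans and matricellular proteins 13 rose and 3, Fbn1, Nov and Wisp1, fell; the former include Postn (periostin), up 16.8-fold (15.8 to 17.9), and Fmod (fibromodulin), up 18.5-fold (16.4 to 20.9). Of 25 collagen and collagen processing genes 8 rose and none fell, with Col3a1 up 24.2-fold (22.9 to 25.7) and the crosslinking enzyme Lox up 3.64-fold (3.53 to 3.76). Matrix metalloproteinases and their inhibitors were split, with 3 of 16 up, the protease genes Adamts1 (39.3-fold, 35.3 to 43.9), Mmp13 (39.0-fold, 33.3 to 45.8) and Adamts5, and 3 down, Mmp16 (15.7-fold, 9.18 to 29.2), Mmp9 and Mmp23. Members named here only to complete a count of 5 or fewer were chosen after their values were seen.

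In the signalling lists, 6 of 21 BMP and TGF-beta genes rose and 1, Inhba, fell; Bmp8a rose 30.2-fold (18.9 to 51.4) and the activin antagonist Fst 282-fold (50.2 to 11191) from 1 count. Of 16 Wnt genes 6 rose and 1, Lgr6, fell, with Axin2, a negative feedback target of the pathway, up 12.99-fold (9.05 to 19.2) and the inhibitor Notum up 7.87-fold (4.65 to 14.2). The FGF, IGF and VEGF list divided into 8 genes up and 7 down of 22: Igf2 rose 29.97-fold (24.2 to 37.5) and Fgfr3 27.1-fold (22.8 to 32.3), and Etv4, a transcription factor downstream of FGF signalling, fell 63.2-fold (21.3 to 309). Notch and Hedgehog genes had 2 of 13 up, Hey1 and Jag2, and 3 down, Hes1, Dll1 and Smo.

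Metabolic lists went in different directions. Glycolysis and hypoxia genes rose in 11 of 25 cases with none down, including Aldoc (36.6-fold, 28.6 to 47.5), Bnip3 (4.99-fold, 4.69 to 5.31) and Ndrg1 (4.62-fold, 4.38 to 4.88). Amino acid response targets of ATF4 fell in 10 of 20 cases with none up; Slc7a11, the cystine transporter, fell 13.7-fold (9.75 to 19.96), Phgdh, the first enzyme of serine synthesis, 4.05-fold (3.71 to 4.43), and Atf4 itself 2.14-fold (2.03 to 2.26). In cholesterol synthesis 6 of 23 genes fell and none rose, among them Nsdhl (3.78-fold, 3.37 to 4.25) and Mvd (2.65-fold, 2.27 to 3.09). Of 10 fatty acid and adipocyte genes, Elovl6 and Acly fell 5.12-fold (4.68 to 5.60) and 2.18-fold (2.10 to 2.27), and Plin4 and Cebpa rose 24.6-fold (18.7 to 33.2) and 7.35-fold (5.38 to 10.2).

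Inflammatory genes fell in 8 of 15 cases and rose in 3, C3 and Tnfaip3 among them. Ccl2, a monocyte chemokine, fell 15.0-fold (8.17 to 30.6) and Ccl7, at 0 counts on day 7, was at least 17.8-fold lower, whereas the complement gene C3 rose 9.58-fold (7.74 to 12.0). Of 20 interferon-stimulated genes 8 fell, such as Ifi44 (9.50-fold, 7.44 to 12.3), and 1, Mx2, rose 9.49-fold (6.99 to 13.2). The median of the interferon list was -0.53 on the log2 scale, and -0.05 over members of 5 CPM or more.

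Proliferation genes stayed within 2-fold: 0 of 36 passed the size rule on day 7, and Mki67 had a log2 ratio of 0.33. Cell cycle inhibitors and p53 targets had 7 of 19 up, led by Trp53inp1 (21.5-fold, 19.4 to 23.9), with Cdkn1a (p21) up 5.39-fold (4.78 to 6.10), and 3 down, Eda2r, Cdkn2b and Sesn2. Immediate early genes rose in 8 of 20 cases, among them Klf2 (21.9-fold, 15.5 to 31.9) and Fos (4.90-fold, 3.64 to 6.70), with Egr2 and Klf4 down, and circadian clock genes in 7 of 17, with Nr1d1 up 4.84-fold (4.33 to 5.42) and Ciart down 3.73-fold (2.88 to 4.89). Lysosome and autophagy genes had 3 of 22 up: Wipi1, Gabarapl1 and Npc1. In the unfolded protein response list only Trib3 of 20 measured genes passed the rule on day 7, falling 7.37-fold (6.07 to 9.01). Cytoskeletal and YAP target genes had 5 of 16 up, Myl9, Lmod1, Des, Acta2 and Actg2 (128-fold, 22.6 to 5098 from 1 count), and 2 down, Ankrd1 and Flna.

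Mitochondrially encoded transcripts had a median log2 ratio of -0.54, with COX1 at -0.50 and ND5 at -0.97, although ND6, the gene on the opposite strand, rose 2.17-fold (2.12 to 2.22). The nuclear-encoded oxidative phosphorylation list had 2 of 27 genes down, Uqcrc1 and Ndufa4. Of 34 ribosomal protein genes only Rpl10a, at 79 counts on day 0 and sharing sequence with pseudogenes, passed the rule. No canonical histone of 15 measured passed it. Among osteocyte and late-stage markers Tnfrsf11b (osteoprotegerin) and Cd44 fell 10.2-fold (5.62 to 20.2) and 3.17-fold (2.92 to 3.44), and the other 6 of 8 stayed within 2-fold.

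Markers of other cell types were few. Of periodontal ligament and fibroblast markers 3 of 10 rose, Postn, Col15a1 and Aspn (6.22-fold, 5.16 to 7.54), and 4 fell, Cd34, Ly6a, Mkx and the tendon factor Scx (46.3-fold, 19.6 to 144). Macrophage and osteoclast markers were low, with Acp5 going from 0 to 59 counts and Mrc1 from 3 to 26. Endothelial markers had Flt1 up 2.56-fold (2.37 to 2.75) and Egfl7 down 4.66-fold (2.24 to 10.9) of 4 measured. Krt8, the sole epithelial marker measured, fell from 47 to 2 counts. Of 3 skeletal muscle markers Tnnt1 rose 26.5-fold (13.2 to 62.2), and of 3 chondrocyte markers Comp rose to 23 counts and Col2a1 fell from 90 to 6. Of 5 neuronal and glial markers 1 rose and 2 fell, with a median of -0.95 (percentile 3.67 of random lists).

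In all, 1568 genes were at least 2-fold higher and 1481 at least 2-fold lower on day 7 than on day 0, of 14694 measured. Scaling by total counts alone shifted the median gene by -0.15 on the log2 scale and gave 1305 higher and 1878 lower, so lists with medians that close to 0 carry no direction here. Time in culture and induction varied together, since no time-matched uninduced culture was analysed here.

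**Figure D2:**
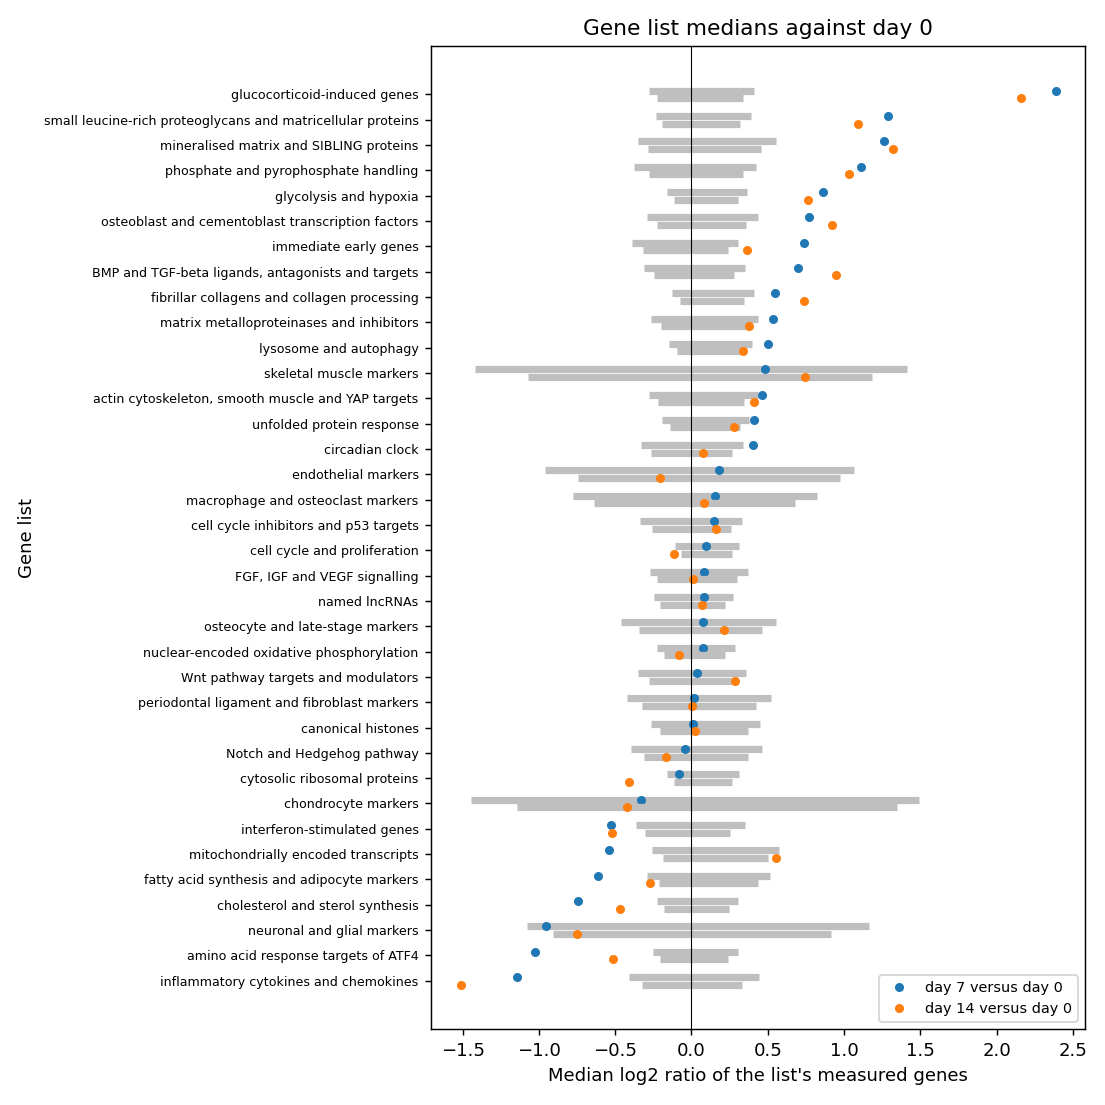
Median log2 ratio to day 0 (horizontal) of the measured genes of each list (vertical), 1 point for day 7 and 1 for day 14, with grey bars for the central 95% of medians of 10000 random gene lists matched on expression. Glucocorticoid-induced genes lay highest of the lists drawn, at 2.39 and 2.16, and inflammatory genes lowest, at -1.14 and -1.51.

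After 14 days Sp7, Ibsp and Alpl, which had risen by day 7, remained above day 0. Sp7 was up 25.5-fold (21.5 to 30.5), Ibsp 203-fold (93.0 to 555), Alpl 5.59-fold (5.18 to 6.05) and Runx2 2.46-fold (2.36 to 2.56), the last having stayed within 2-fold on day 7. Spp1 (0.24), Col1a1 (0.37) and Mki67 (0.47 on the log2 scale) were within 2-fold, and Dmp1 was down 2.93-fold (1.34 to 7.08). Among genes of 10 CPM or more H19 remained that with the largest ratio, at 13475 counts against 2, 6899.7-fold (1909.7 to 56979), followed by Tnn with 3307 counts. Slc36a2, a proton-coupled amino acid transporter gene, was up 542-fold (185 to 2631) from 3 counts. The lowest genes relative to day 0 were Msln (48.4-fold, 27.5 to 94.2), Vcam1 (29.1-fold, 18.7 to 48.1), Etv4 (64.8-fold, 21.8 to 317, from 3 counts on day 14) and Ccnd1 (27.1-fold, 17.2 to 45.4), with Selp at 3 counts against 177, 57.6-fold (19.4 to 282).

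By list, 17 of 17 glucocorticoid-induced genes were up on day 14, the metallothionein gene Mt2 (2.70-fold, 2.56 to 2.86) among them. BMP and TGF-beta genes had 10 of 21 up, with Smad9, a BMP pathway SMAD, at 3.12-fold (2.83 to 3.45), and 1, Inhba, down. Transcription factors had 8 of 17 up and 1, Twist2, down, mineralised matrix genes 8 of 13 up and 1, Dmp1, down, and proteoglycan and matricellular genes 12 of 22 up and 2, Fbn1 and Nov, down. Phosphate handling genes had 6 of 11 up and glycolysis and hypoxia genes 8 of 25, with none down in either. Collagen genes had 5 of 25 up: Col3a1, Loxl1, Lox, Plod2 and P4ha2, and none down. ATF4 targets had 5 of 20 down, Slc7a11, Phgdh, Psat1, Slc7a5 and Psph, and 2 up, Ddit4 and Cebpb, and cholesterol synthesis 3 of 23 down: Mvd, Nsdhl and Tm7sf2, with none up. Inflammatory genes had 8 of 15 down and 3 up, C3 and Tnfaip3 among them, with a median of -1.51 that was -0.30 over members of 5 CPM or more; interferon-stimulated genes had 7 of 20 down, 2, Mx2 and B2m, up and a median of -0.52, or -0.22 over such members. Ribosomal protein genes had a median of -0.41 with no member past the rule. Again 0 of 36 proliferation genes passed the size rule, though their median was -0.12, at percentile 0.6 of random lists, with 26 members below 0. Mitochondrial transcripts had a median of 0.55, on the other side of 0 from day 7.

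On day 14 1205 genes were higher and 977 lower than on day 0, of 14593 measured; with total counts alone, which shifted the median gene by -0.16, the split was 1019 to 1300. A shared day 0 library links both comparisons. Of the changed genes, 983 were higher in both, against 126.8 for independent lists. In 20 sets of simulated unchanged libraries, each with 1 drawn day 0 library for both comparisons, at most 3 were. The genes lower in both were 824, against 97.1 and at most 2. These sets hold counting error alone, so a day 0 library that departs for any other reason is not covered. How much of the excess comes from the shared control cannot be told, because 1 library cannot be split.

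Between day 7 and day 14 the gene libraries differed little, with 242 genes higher and 183 lower on day 14. Genes that rose included Rny1, a small Y RNA (16.7-fold, 14.3 to 19.6), and, having fallen by day 7, Mest (5.78-fold, 3.80 to 9.13), Slc7a11 (5.07-fold, 3.52 to 7.51), Kif26b (4.30-fold, 3.57 to 5.22) and Nav3 (4.09-fold, 2.84 to 6.02). Igf1, an anabolic growth factor of bone, rose 3.59-fold (2.90 to 4.48) and Tnfrsf11b 6.51-fold (3.53 to 13.1). Genes that fell included Jph2 (2.24-fold, 1.93 to 2.62) and Car9 (2.17-fold, 2.09 to 2.24), with Tmem8b at 61 against 155 counts; Psmb6, counted on an alternate scaffold that shares its sequence with the chromosome, is uncertain. Of the lists, 5 of 12 mitochondrial transcripts rose, ND2, ND4, ND5, ND1 and CYTB, with ND1 up 2.28-fold (2.24 to 2.33) and CYTB up 2.16-fold (2.12 to 2.20), as did 4 of 20 interferon-stimulated genes, Gbp3, Ifi44, Ifit1 and Isg15. Against day 0, no gene higher on day 7 was lower on day 14, and 1 gene went the other way: Fbxo40, singled out after its values were seen, which was lower on day 7 (-1.02) and higher on day 14 (1.22 on the log2 scale). Across 10338 genes the Spearman correlation of CPM was 0.981 between day 7 and day 14, 0.874 between day 7 and day 0 and 0.908 between day 14 and day 0; genes are not independent replicates.

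Long non-coding RNAs leaned upwards in both comparisons with day 0. Besides H19, A530020G20Rik rose 174-fold (59.3 to 848) from 3 counts on day 7, LOC101056001 47.2-fold (21.4 to 129.8) and Gm35775 35.6-fold (18.5 to 78.5); Gm36876, at 0 counts on day 0, was at least 46.9-fold higher. E230016K23Rik fell 80.0-fold (14.0 to 3199) to 1 count, A230057D06Rik 30.8-fold (10.2 to 152) to 3 counts and LOC108168326 13.6-fold (8.06 to 24.7), while Gm26901 went from 71 to 0 counts, at least 22.6-fold lower. Of 35 long non-coding RNAs of the fixed list, 5 rose on day 7, H19, Carmn, Malat1 (2.12-fold, 2.11 to 2.13), Dnm3os, the precursor of miR-199a-2 and miR-214 (2.09-fold, 1.96 to 2.23), and Lncpint (2.69-fold, 2.33 to 3.11), and 1, Bvht, fell. In all 347 rose and 144 fell by day 7, of 1426 measured, and 233 and 95 by day 14 (199 and 130 with total counts alone); between day 7 and day 14 44 rose and 49 fell (33 and 56 from the deposited FPKM values). Whether counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be separated and these values are uncertain for such genes.

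Among mature miRNAs, the library labelled day 7 stood apart. The hypoxia-induced miR-210-3p was 10.6-fold (95% counting interval 10.5 to 10.7) lower in the library labelled day 7 than in that labelled day 0, miR-205-5p 25.8-fold (22.5 to 29.7), miR-181a-5p 10.8-fold (10.7 to 10.9), miR-195a-5p 10.2-fold (9.82 to 10.6) and miR-497a-5p 8.90-fold (8.32 to 9.51). Higher in it were miR-155-5p (18.6-fold, 16.9 to 20.5), miR-344-3p (4.24-fold, 4.08 to 4.40), miR-146a-5p (3.91-fold, 3.77 to 4.06), miR-125b-1-3p (3.20-fold, 3.07 to 3.33), the muscle miRNA miR-206-3p (2.79-fold, 2.71 to 2.88) and miR-7a-5p (2.55-fold, 2.53 to 2.57). miR-148a-3p, the most abundant miRNA in the mean, stood at 71196 CPM here, against 234080 and 266650 in the libraries labelled day 0 and day 14. miR-21a-5p, at 78957 CPM in the library labelled day 0, had a log2 ratio of -0.01. All these ratios depend on the scaling, whose error the counting intervals leave out. With total counts alone the median miRNA shifted by 0.75 on the log2 scale for day 7 against day 0. The log2 ratios were then -2.66 for miR-210-3p, -0.96 for miR-148a-3p (within 2-fold) and 2.10 for miR-7a-5p.

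By family, all 6 members of the miR-199 and miR-214 cluster were at least 2-fold lower in the library labelled day 7 than in that labelled day 0 (median log2 ratio -1.44), as were 2 of 3 of the miR-181 family (-2.14) and 4 of 6 of the miR-143, miR-145, miR-221 and miR-222 group (-1.08). In the cluster miR-199a-3p and miR-199b-3p had nearly the same log2 ratio, -1.54 and -1.55. Whether they count the same reads was not checked. With total counts alone the medians of the cluster and of the miR-143, miR-145, miR-221 and miR-222 group were -0.69 and -0.32. Those of the let-7 and miR-30 families changed sign, from -0.32 to 0.43 and from -0.59 to 0.16, and that of the miR-17 to 92 family went from 0.02 to 0.77. The let-7, miR-30 and miR-17 to 92 families had no member past the rule on that comparison, and the miR-29 family had miR-29c-3p lower. Of 13 miRNAs reported to favour osteoblast differentiation 4 were lower, including miR-322-5p (2.94-fold, 2.89 to 3.001), and none higher. The median of that list was -0.40, at percentile 52.995, and 0.35 with total counts. Of 14 reported to restrain it 2 were higher, miR-155-5p and miR-206-3p, and 2 lower, miR-214-3p and miR-31-5p; the median was -0.44, at percentile 43.81, and 0.31 with total counts. Among 7 miRNAs of other cell types the muscle miRNA miR-1a-3p was 28.4-fold (22.0 to 37.3) lower in the library labelled day 7, at 62 counts. The blood cell miRNA miR-142a-3p was 2.11-fold (2.03 to 2.20) lower in it, while miR-206-3p was higher. The median of that list was -0.76, and 0.51 over members of 50 CPM or more. With total counts alone miR-322-5p (-0.80), miR-214-3p (-0.58), miR-31-5p (-0.68), miR-29c-3p (-0.30) and miR-142a-3p (-0.32) were within 2-fold on the log2 scale. No member of the miR-200 family or of the Dlk1-Dio3 cluster reached the minimum of 10 CPM in the mean, and neither of the 2 measured members of the miR-34 family, miR-34a-5p (-0.33) and miR-34c-5p (0.70), passed the rule.

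**Figure D3:**
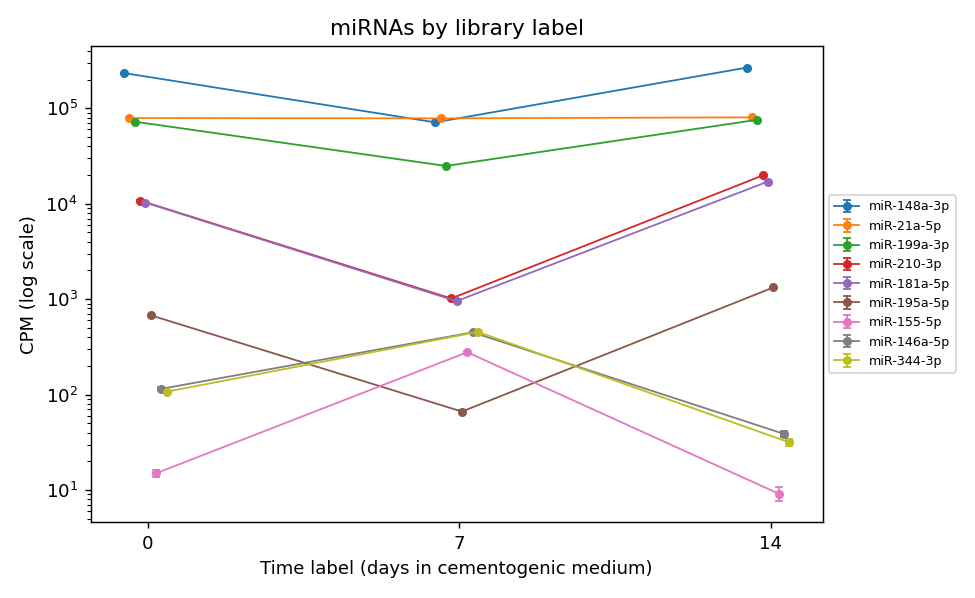
CPM on a log scale (vertical) of 9 mature miRNAs in the libraries labelled 0, 7 and 14 days (horizontal), 1 library per point, with bars for exact 95% Poisson intervals of the count and points set slightly apart for legibility. miR-210-3p, miR-181a-5p and miR-195a-5p dip and miR-155-5p, miR-146a-5p and miR-344-3p peak in the library labelled day 7.

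The libraries labelled day 14 and day 0 were close. Of miRNAs of 100 CPM or more, those with the largest ratios downwards in the library labelled day 14 were miR-344-3p (3.40-fold, 3.09 to 3.73), miR-146a-5p (2.96-fold, 2.72 to 3.23), miR-3963 (2.73-fold, 2.52 to 2.96), miR-344b-3p, miR-3968 and miR-1900. No miRNA at that level passed the rule as higher in that library. The 2 below that level that did, miR-139-5p and miR-499-5p, were named after their values were seen. Compared with the library labelled day 7, that labelled day 14 had miR-181a-5p 17.9-fold (17.7 to 18.1) higher, miR-210-3p 19.4-fold (19.2 to 19.6) higher and miR-155-5p 30.3-fold (25.8 to 35.9) lower. The size rule was passed by 99 of 385 miRNAs for labels day 7 and day 0 (24 higher, 75 lower), 20 of 376 for day 14 and day 0 (2 and 18) and 137 of 384 for day 14 and day 7 (83 and 54). This split depended on scaling: with total counts alone it was 104 higher and 17 lower for day 7 and day 0, and 24 and 143 for day 14 and day 7. The median miRNA shifted by 0.75 for day 7 and day 0, -0.12 for day 14 and day 0 and -0.87 for day 14 and day 7 on the log2 scale, and 41 and 78 of the calls for the first and last pair were shared with those above. The Spearman correlation across 392 miRNAs was 0.984 between the libraries labelled day 14 and day 0, 0.940 between day 7 and day 0 and 0.905 between day 14 and day 7.

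As labelled, the host genes H19 and Dnm3os moved apart from miRNAs processed from them between day 0 and day 7. H19 went from 0.141 to 1931 and 969.9 CPM, whereas miR-675-3p had 34, 3 and 65 counts and miR-675-5p 33, 2 and 49 in the libraries labelled day 0, 7 and 14; both were named after their values were seen. Dnm3os rose while miR-199a-3p (2.91-fold, 2.91 to 2.92) and miR-214-3p (2.52-fold, 2.498 to 2.55) were lower in the library labelled day 7. With total counts alone the log2 ratios of both miRNAs were within 2-fold, at -0.79 and -0.58. Only miR-214-3p and miR-214-5p were assigned to Dnm3os in the comparison of hosts below. Car9 and other hypoxia genes rose while miR-210-3p was lower, but Car9 was not among the hosts compared. Hosts and miRNAs were compared across 46 genes that host miRNAs on the same strand and passed the size rule in at least 1 comparison. Their miRNAs needed 20 counts in at least 1 library, without the CPM minimum of the miRNA calls. Some hosts rest on few miRNA counts, such as Slit2 (7, 29 and 1 in the libraries labelled day 0, 7 and 14) and Plpp2 (6, 20 and 3). Others had many, such as Dnm3os (154363, 87753 and 100941). Well-counted miRNAs alone were not tested. Host and miRNA changes from day 0 to day 7 were opposed as labelled, with a Pearson correlation of -0.597 (95% interval from resampling hosts -0.736 to -0.476). It was 0.435 for day 14 against day 0 and -0.550 for day 14 against day 7; genes are not independent replicates.

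**Figure D4:**
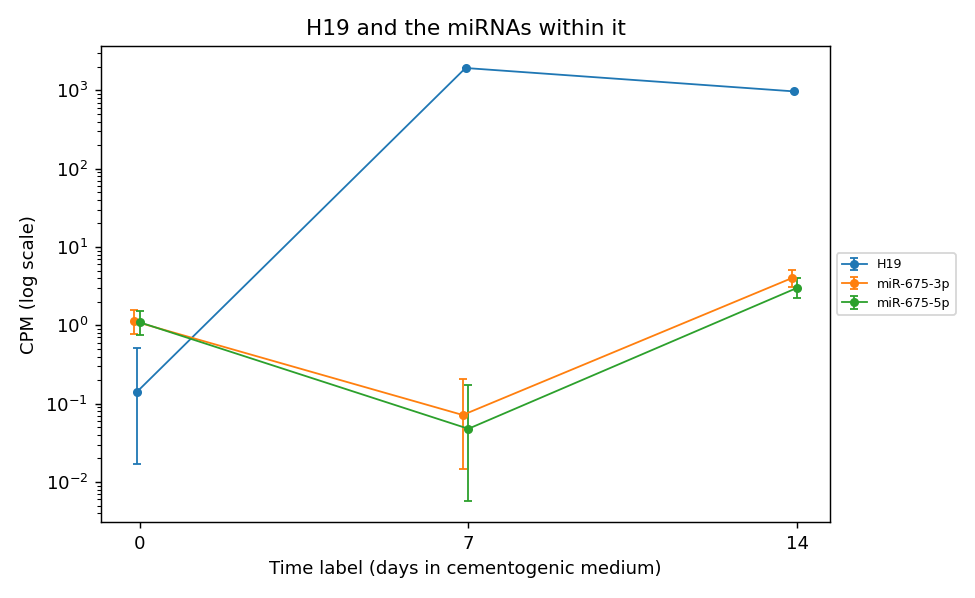
CPM on a log scale (vertical) of H19 and of miR-675-3p and miR-675-5p in the libraries labelled 0, 7 and 14 days (horizontal), 1 library per point, with bars for exact 95% Poisson intervals of the count. H19 is highest on day 7, where the miRNA library so labelled has 3 and 2 counts of the pair.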

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

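The host gene test and the test of shifted miRNA labels were chosen only after the result was seen. In 32 named features the counting intervals put day 7 and day 14 on opposite sides of day 0, and the day 14 to day 7 ratio passed the size rule; with 1 library per time point that difference was not tested. With total counts alone all 4 genes and 17 of 28 miRNAs still met both conditions: 11 miRNAs were within 2-fold between day 14 and day 7, and 5 of these were no longer on opposite sides of day 0 (miR-142a-3p, miR-143-5p, miR-199a-3p, miR-199b-3p and miR-26a-5p). With DESeq2 size factors 27 miRNAs met both, and miR-7a-5p was no longer on opposite sides. The values given are log2 ratios of day 14 to day 7. Of 4 genes, the mitochondrial transcripts ND5 (1.42), ND1 (1.19) and CYTB (1.11) were lower on day 7 and higher on day 14, and Tmem8b (-1.29) went the other way.

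The other 28 were miRNAs, and whether miR-199a-3p and miR-199b-3p among them count the same reads was not checked. Lower in the library labelled day 7 and higher in that labelled day 14 were miR-1a-3p (5.28), miR-195a-5p (4.31), miR-210-3p (4.28), miR-181a-5p (4.16), miR-497a-5p (3.76), miR-181b-5p (2.51), miR-199a-5p (1.94), miR-148a-3p (1.91), miR-214-3p (1.65), miR-145a-5p (1.62), miR-199b-3p (1.61), miR-199a-3p (1.61), miR-143-3p (1.45), miR-142a-3p (1.23), miR-143-5p (1.14), miR-30b-5p (1.13), miR-142a-5p (1.09), let-7b-5p (1.04) and miR-26a-5p (1.02). Higher in the library labelled day 7 were miR-155-5p (-4.85), miR-344-3p (-3.83), miR-146a-5p (-3.52), miR-125b-1-3p (-2.79), miR-3963 (-2.15), miR-344b-3p (-1.85), miR-126a-3p (-1.75), miR-3968 (-1.73) and miR-7a-5p (-1.42). Of all 32, miR-125b-1-3p, miR-146a-5p and miR-344-3p passed the size rule against day 0 on both days.

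The miRNA library labelled day 7 stood apart from the other miRNA libraries, whereas in the gene counts the day 0 library stood apart. The tables argue against unequal depth of the small RNA libraries as the source, since the library labelled day 7 had the middle total. After thinning, the count of 2-fold differences of day 7 against day 0 was 5.76 times that of day 14 against day 0 (98 and 17). Thinning could change few calls, because a miRNA already needed 10 CPM to be counted. Base composition was addressed only in part. The trend of the log2 ratio with GC content spanned 1.27 for day 7 against day 0, and 0.346 for day 14 against day 0. After its removal the ratio of the counts was 4.33 (78 and 18), so overall GC content alone did not account for the pattern. Other biases of sequence were not tested. Across 46 host genes the host and miRNA changes from day 0 to day 7 had r = -0.597 as labelled, with 34 hosts moving against their miRNA. A candidate explanation is that miRNA labels were exchanged between day 0 and day 7. The r from day 7 to day 14 would then be -0.623 (-0.774 to -0.367), so hosts and miRNAs would move apart there. Mature miRNAs still accumulating after their hosts had peaked could give that sign, but this was not tested. The exchange also did not give the highest agreement of profiles of the 6 assignments. On these hosts it is less favoured than the shift described next. It is left open because some hosts rest on few miRNA counts. A shift of the 3 labels by 1 place in the order of the deposited columns would make the libraries labelled day 7, 14 and 0 those of day 0, 7 and 14. This shift gave the highest agreement of profiles of 6 assignments (0.627, against 0.518 for the exchange and -0.209 as labelled). Best minus second was 0.108 (0.0479 to 0.209). The agreement of profiles was not computed without H19 or by rank. The shift needs a positive correlation of the host change from day 7 to day 14 with the ratio of the miRNA libraries labelled day 0 and day 14. That correlation was 0.623 (0.367 to 0.774), 0.585 without H19, and 0.433 as a Spearman correlation. The value of 0.623 is the same statistic as the -0.623 of the exchange with its sign reversed, not separate evidence. The shift may account for the pattern as a hypothesis found and tested on the same data, with hosts of few miRNA counts included. Seed sites left the exchange open, with targets moving with the labelled change in 63.6% of 22 families and a median absolute difference of 0.00881 between genes with and without a site on the log2 scale; a biological difference of the miRNA time course remains untested, and no comparison under other labels is reported.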

How the results depend on the processing

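Thinned miRNA libraries, gene totals without mitochondrial and small structured RNA genes, and factors without the library labelled day 7 were chosen after seeing the data; none moved a count by over 1.5 times. Of alternative counts of different features, 61 stayed within 1.5 times the main value and 30 did not; of list medians 733 stayed, 40 moved and 1, outside the central 95% of medians of random lists at first, reversed; of named features 2667 stayed within their counting interval and 1473 moved. Called or not, the sign changed in 73 list medians, 30 of them with total counts alone, and in 146 values of named features, 70 with total counts alone. No named feature past the size rule changed sign. With 5 times the minimum, which leaves fewer low features, 2019 genes, 159 long non-coding RNAs on day 7, 1359 and 104 on day 14, 11 miRNAs in the library labelled day 14, and 139 and 11 for day 14 against day 7 passed. With a pseudocount of 2, which shrinks low ratios, these were 1964 and 171, 1360 and 107, and 91 and 5. A 4-fold threshold, stricter by construction, left 776, 563 and 16 genes, 97, 50 and 1 long non-coding RNAs, 18, 1 and 33 miRNAs for day 7 and day 14 against day 0 and day 14 against day 7, and 477 genes changed the same way on both days. With no minimum, which adds low features, 164, 43 and 241 miRNAs and, for day 14 against day 7, 146 long non-coding RNAs passed. A pseudocount of 0.1 gave 682 genes and 159 long non-coding RNAs for day 14 against day 7, and the deposited FPKM values 209 long non-coding RNAs for day 14 against day 0; the cause was not tested. The median of the miR-17 to 92 list for the libraries labelled day 14 and day 7, -0.02, was 0.00531 with DESeq2 size factors, so it carries no direction. The DESeq2 Wald test, leaving out each column and the replicate block were not run, since they needed replicated columns. No paired analysis was possible because each time point has 1 library and the columns carry no replicate number. Depth limits features near the floor of 3 counts.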

Other observations

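The test of small structured RNAs was chosen only after the result was seen. Orm1, Trdn, Sema3e, Ccnd3, Grb10, Plagl1, Igf2r and Rn18s-rs5 were chosen after their values were seen. Serping1 and C3, genes of the complement system, rose on both days, and Orm1, an acute phase glycoprotein gene, went from 0 to 527 and 388 counts. Trdn (triadin), a gene of the calcium release unit of striated muscle, went from 0 to 632 and 573 counts.

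Sema3e, a guidance gene like Sema3a and Sema3c, fell on both days (log2 ratios -3.88 and -2.57). Ccnd3 had ratios of 0.26 and -0.11 where Ccnd1 and Ccnd2 fell, and no gene of the proliferation list passed the size rule. Among imprinted genes Grb10, an inhibitor of insulin and IGF receptors, rose (2.83 and 2.86) with H19 and Igf2, Mest fell (-3.84 and -1.58), and Plagl1 (-0.61 and 0.82) and Igf2r (0.28 and 0.11) did not pass the rule.

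Rny1 and the ribosomal RNA gene Rn18s-rs5 (47, 69 and 1688 counts) were higher in the day 14 library than in both others. A general carry-over of small structured RNA into that library would raise the others of that class, but the median day 14 to day 7 log2 ratio of 60 such RNAs was -0.17, with a median absolute deviation of 0.431. The share of counts on genes typed snRNA was nevertheless 0.929%, 1.24% and 1.62% on day 0, 7 and 14. The 60 RNAs leave out Rny1 and Rn18s-rs5 themselves, so incomplete removal of ribosomal RNA was not tested. No biological explanation of the rise of Rny1 and Rn18s-rs5 was tested.

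The day 0 gene library differed from both induced libraries while these were alike, a pattern in which induction and time in culture vary together. Other cells in the day 0 library would differ in positional genes, and 1 of 15 Hox and Y-linked genes of 1 CPM or more, Hoxc6, differed 8-fold or more between day 7 and day 0, against 4 or more foreseen. The counting intervals of 4, taken into account only after the result was seen, reached 8-fold, so the test left this open. Scaling did not account for it, since the count of day 7 against day 0 was at least 7.20 times that of day 14 against day 7 under DESeq2 size factors and total counts. A response to the medium or to time in culture was not tested, as no uninduced culture of the same age was analysed here.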
